A study of Mus musculus with 8 samples.

How the data were processed

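The 8 libraries are single-cell RNA libraries of mouse hippocampus, from a strain, tissue, sex and treatment that the labels name. Per the labels' protocol, tissue was dissociated with pronase and DNase and the cells were purified by density gradient centrifugation; no sort is described. The submitters' processing notes name bcl2fastq, Cell Ranger 3.1.0, Seurat 3.2.2 and the mm10 build, without the role or order of each. The values used are the UMI counts per gene and barcode that the authors deposited for each library, which are whole numbers, not normalised, over 27998 genes. A combined deposited matrix of 45693 cells was used only for its barcodes, because its column names do not tie cells to samples. Of the library barcodes 45918 matched it by barcode sequence alone. Its effect on the results is given as an alternative. Gene positions are from GENCODE vM21 on mm10, counted from 1; 27722 of the 27998 genes (99.0%) matched by identifier, and 121 symbols were shared by more than 1 gene.

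Per library, 17775596 to 62898636 UMIs stood on 4413 to 19089 barcodes. Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, 64934 in all. Doublets were called with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. Where the caller marked under 0.5% of cells, as it did in VPA female replicate 4 with 0 marked, its own threshold was not used and cells scoring above the quantile that leaves the top 6% were removed, 1013 in that library (5.48%). Over all libraries 2467 cells were removed and 62467 stayed. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 with seed 7. Clusters were named from marker genes set before the data were examined, as were the groups, tests, gene lists and the rule for naming genes. A cluster needed at least 3 detected markers, and stayed unnamed where its leading genes went against its name or its median UMI count, times 3, lay under that of its own sample with no marker among its top 10 genes. Thresholds on marker scores and on clusters drawn mostly from 1 library were set after the data were seen; the shares of the clusters left unnamed are given by group. Cells with a high haemoglobin share were set apart.

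Counts were summed for each library and class, since cells are not replicates, and tested with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filterByExpr, Benjamini-Hochberg adjustment within each class, threshold 0.05) in the 10 classes with at least 20 cells in each of the 8 libraries. VPA against saline and male against female came from a model with treatment and sex; the difference of the VPA effect between the sexes and the effects within a sex came from a model of the 4 groups. All adjusted p-values of genes and shares are from edgeR unless another tool is named. Shares of cells were tested with edgeR on cell numbers and by an exact permutation test over 70 splits, whose smallest p is 0.0286. Wilson intervals at 95% and the limit of 3 counts for a share of 0 cover counting error only. Replicates were compared first, and no pair of libraries agreed within sampling noise: the chi-square per gene lay between 16.6 and 336.

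Gene lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, over 272 class-list pairs, and again with an estimated correlation and with fry. The lists reported are those of autism-associated, myelin, interferon response, heat shock, immediate early, glutamatergic synapse, nuclear oxidative phosphorylation, reactive astrocyte, cholesterol synthesis, inflammatory cytokine and NF-kB, blood-brain barrier, ribosomal protein, histone deacetylase, Wnt, and X-inactivation and escape genes. List tests for male against female were added to those planned. Genes named in the text are, for each contrast and class, the 3 highest and 3 lowest log2 fold changes among those past the threshold at a mean log2 CPM of at least 5, with at most 30 for each contrast and, for VPA against saline, the same sign in both sexes. To these were added genes called in at least 3 classes, the 2 genes of smallest p where a class had no call, the 4 members of smallest p of each list called by camera, the Y-linked genes and Xist, and called autism-associated genes. Predicted genes were counted but not named, some genes that the rule picks are not reported, and any other gene is said to have been chosen after its value was seen.

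The test was tried on simulated counts drawn from the real means and library sizes with 200 changed genes in each class. The changed genes were taken only from well-counted ones, so the recovery of genes with few UMIs was not tried. For VPA against saline, 19% to 90% of 2-fold and 91% to 100% of 4-fold changes were recovered, and for the difference between the sexes 0% to 14% and 0% to 87%. False calls were 2.6% to 7.7% and 0% to 13% of those made, against a threshold of 5%. Alternatives were other size factors, no count filter, a stricter cell filter (500 genes, 10% mitochondrial UMIs), doublets kept, equal cells per library, cells of the combined matrix, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, and leaving out each library. Added after seeing the data were leaving out VPA male replicate 1 and VPA female replicate 4 together, leaving out 1 endothelial-like cluster or the Plvap-rich sub-cluster, and a denominator without choroid plexus-like and unnamed cells. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3. RNA reads, batches and animals of origin were not analysed here.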

Results

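RNA of single hippocampal cells was measured in C57BL/6 mice of both sexes that had been exposed before birth to saline or to valproic acid (VPA). VPA is an anticonvulsant that inhibits histone deacetylases and is used in rodents to model traits of autism. There were 8 libraries, 2 for each sex and treatment, and each is named here by treatment, sex and the replicate number of its title. The labels give them as separate samples but say nothing of separate animals, litters or age, so p-values measure only the spread between these samples, which may be technical. The libraries held 67678 barcodes. Saline male replicates 1 and 2 held 33033589 and 17775596 unique molecular identifiers (UMIs). Saline female replicates 3 and 4 held 38973772 and 25762772. VPA male replicates 1 and 2 held 62898636 and 32290325. VPA female replicates 3 and 4 held 36106803 and 52212459. Xist, the RNA that silences the second X chromosome (chromosome X, 103460366 to 103483254, minus strand), was read at 895 to 1050 CPM (counts scaled to the same total in every library) in the 4 libraries labelled female and at 0.163 CPM or less in the 4 labelled male. The Y-linked translation factor gene Eif2s3y was read at 66.3 to 82.4 CPM and the RNA helicase gene Ddx3y at 36.1 to 60.9 CPM in the male libraries, and neither had a UMI in a female one. Of the other Y-linked genes, the histone demethylase genes Uty and Kdm5d had 1 UMI each in VPA female replicate 3 and none in the other female libraries.

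The 62467 cells kept fell into 43 clusters, of which 36 carried enough markers to be named, in 17 classes. Oligodendrocyte-like, endothelial-like and microglia-like cells were among them, as were pericyte-like, smooth muscle-like and neuron-like cells. The 7 clusters without a name held 11440 cells and made up 57.7% of the cells of VPA female replicate 4 (Wilson 95% interval 57.0 to 58.4), where the median cell held 1341 UMIs. In the other 7 libraries the median was 2988 to 4993 UMIs. The largest unnamed cluster, of 4750 cells, carried choroid plexus markers and held on average 0.254% of cells in saline male, 0.106% in saline female, 0.423% in VPA male and 13.5% in VPA female libraries. The last mean rests on VPA female replicate 4, at 26.3%, with 0.760% in VPA female replicate 3. The second, with oligodendrocyte markers, held 0.489%, 0.560%, 0.565% and 10.3% in the same order, and 19.9% in VPA female replicate 4 against 0.798% in VPA female replicate 3. The smaller ones held on average between 0.0485% and 2.65% of the cells of any group.

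Whether prenatal VPA changed the makeup of the hippocampal samples was asked first. Choroid plexus-like cells, the epithelium that secretes cerebrospinal fluid, made up 4.43 ± 1.77% of cells in VPA libraries and 0.938 ± 1.00% in saline ones (SD, n = 4 each), and all 4 VPA libraries lay above all 4 saline ones. None were seen among the 7387 cells of saline female replicate 3, which allows a share of up to 0.0406%. Microglia-like cells, the resident immune cells of the brain, made up 4.33 ± 2.45% after VPA and 10.3 ± 5.26% after saline. Excitatory neuron-like cells made up 1.65 ± 1.09% and 4.03 ± 2.35%, endothelial-like cells 24.1 ± 10.5% and 39.7 ± 14.4%, and oligodendrocyte-like cells 26.9 ± 13.2% and 16.0 ± 9.35%. None of the 17 classes passed the edgeR quasi-likelihood test after adjustment (smallest adjusted p = 0.237), and 3 had an unadjusted p under 0.05. The smallest, 0.0193, belonged to macrophages of the brain borders, with mean shares of 0.286% and 0.967% (log2 fold change -1.72 ± 0.65). The exact permutation test called 0 after adjustment and 1 before it. That 1 was the choroid plexus-like class, with a log2 fold change of 2.24 ± 1.01 (SE). Its exact two-sided permutation p was 0.0286, the smallest that 70 splits allow, and its adjusted exact p was 0.291. Without saline male replicate 1 edgeR called 1 class, the choroid plexus-like one. With the unnamed cluster of choroid plexus markers added, the shares were 11.4 ± 12.7% and 1.12 ± 1.16% (exact permutation p = 0.0286). Of the VPA libraries, VPA female replicate 4 held 30.2% and the others 2.56% to 7.04%.

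**Figure D1:**
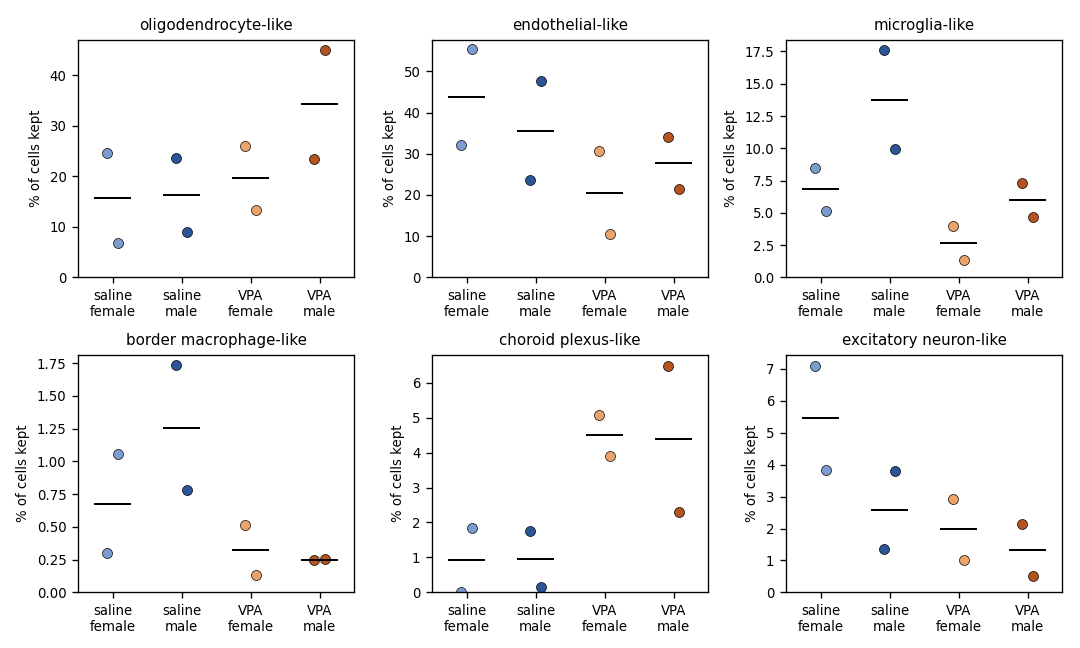
Percent of all cells kept (vertical axis) in 6 classes, with 1 point for each library and a bar at each group's mean, by treatment and sex. The choroid plexus-like panel shows all 4 VPA libraries above the 4 saline ones, at 4.43% against 0.938% on average; no class passed edgeR's test after adjustment.

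Between the sexes, smooth muscle-like cells made up 5.59 ± 1.71% of cells in male and 2.76 ± 0.827% in female libraries (n = 4 each), and microglia-like cells 9.88 ± 5.57% and 4.75 ± 2.95%. The smooth muscle-like class had an exact permutation p of 0.0286 and an adjusted exact p of 0.486. By edgeR 0 of 17 classes passed (smallest adjusted p = 0.495), 0 had an unadjusted p under 0.05, and the exact test called 0 after adjustment. The VPA effect on a share did not differ between the sexes for any of the 17 classes by edgeR (smallest adjusted p = 0.836). Of the 17, 0 had an unadjusted p under 0.05, and no other tool was run on this difference.

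Genes were then compared between VPA and saline within the 10 classes that had at least 20 cells in every library. Ttr, which encodes the thyroid hormone carrier transthyretin of the choroid plexus (chromosome 18, 20665280 to 20674321, plus strand), rose in 3 classes. In pericyte-like cells it went from 99.2 ± 117 to 3730 ± 2020 CPM (SD, n = 4 each), a log2 fold change of 5.08 ± 0.67 (SE; adjusted p = 0.00096). The log2 fold change was 4.03 ± 0.53 in smooth muscle-like cells (adjusted p = 0.00092) and 5.03 ± 0.73 in committed oligodendrocyte precursor-like cells (adjusted p = 0.012). In the other 7 classes its estimate lay between 3.64 and 4.53 without passing the test. In oligodendrocyte precursor (OPC)-like cells Ttr did pass by limma-voom (5.62, adjusted p = 3.4e-06), with the replicate block (4.26, 6.6e-07) and with equal cells per library (3.89, 1.3e-06). It also passed there with the stricter cell filter (0.035), with doublets kept (0.040) and with the cells of the deposited combined matrix (0.022). The same held without saline female replicate 3 (0.022), saline female replicate 4 (0.0062), VPA male replicate 1 (0.0079), VPA male replicate 2 (5.9e-05), VPA female replicate 3 (0.044) or VPA female replicate 4 (0.020). Beside this, Ttr over all cells ranged from 0.632 CPM in saline female replicate 3 to 110423 CPM in VPA male replicate 1, and the choroid plexus-like share was higher in each VPA library. The DESeq2 test called Ttr in none of the 3 classes (adjusted p of 0.86 to 1.0). The pericyte-like call was lost with the cells of the deposited combined matrix (4.84, adjusted p = 0.058), and the smooth muscle-like one without VPA male replicate 1 and VPA female replicate 4 together (3.04, adjusted p = 0.15).

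In smooth muscle-like cells 4 genes of myelin rose. Mal, a myelin membrane protein, rose by a log2 fold change of 1.82 ± 0.29 (adjusted p = 0.0048). Car2, a carbonic anhydrase, and Trf, which encodes transferrin, rose by 2.01 ± 0.33 and 1.60 ± 0.29 (adjusted p = 0.0055 and 0.021). Of the 13 myelin genes measured in these cells all 13 had a higher estimate after VPA (median 1.60). Of them 4 passed the test over all genes and 10 when adjusted over the list alone. Markers of oligodendrocytes stood at 3.145 to 4.048 log2 CPM in saline and 3.742 to 5.634 in VPA libraries. These markers are all on the myelin list too, so here and below they are no separate evidence beside it. The list was called by camera in smooth muscle-like cells (adjusted p = 3.7e-46) and lost with an estimated correlation (adjusted p = 0.359 with an estimated correlation). In endothelial-like cells 19 of 20 myelin genes had a higher estimate (median 1.78), with 1 passing over all genes and 18 adjusted over the list alone (camera adjusted p = 2.4e-35; adjusted p = 0.515 with an estimated correlation). Oligodendrocyte markers stood there at 3.470 to 4.969 log2 CPM in saline and 5.100 to 6.553 in VPA libraries. In immature neuron-like cells it was 16 of 16 (median 2.85, 16 adjusted over the list alone, camera adjusted p = 1.2e-13; adjusted p = 0.779 with an estimated correlation). There VPA female replicate 4 stood apart, at a mean of 8.986 log2 CPM. The other VPA libraries stood at 3.850 to 6.122 and the saline ones at 3.795 to 5.655. Oligodendrocyte markers, a part of the same list, stood at 9.286 in VPA female replicate 4. They stood at 4.146 to 6.555 in the other VPA libraries and 4.069 to 5.867 in saline ones. Oligodendrocyte-like cells had shares of 26.9 ± 13.2% and 16.0 ± 9.35% in VPA and saline libraries. Mal was lost with predicted doublets kept (1.73, adjusted p = 0.074).

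In endothelial-like cells 26 genes rose and 1 fell after VPA. Plpp3, a lipid phosphate phosphatase (chromosome 4, 105157347 to 105232764, plus strand), went from 24.7 ± 4.87 to 45.6 ± 9.89 CPM (0.89 ± 0.14, adjusted p = 0.015). Aplp1, a neuronal relative of the amyloid precursor protein, went from 24.3 ± 10.6 to 60.8 ± 16.0 CPM (1.35 ± 0.26, adjusted p = 0.046). Its highest level, 3830 CPM, was in oligodendrocyte-like cells, whose markers were also higher in the endothelial-like cells of VPA libraries. The next 3 genes lay below the expression level set for naming genes and were chosen after their values were seen. Plvap, the diaphragm protein of fenestrated capillaries (chromosome 8, 71497765 to 71511752, minus strand), rose by 4.28 ± 0.49 (adjusted p = 0.00098). Esm1, a marker of endothelial tip cells, rose by 6.44 ± 0.55 (adjusted p = 5.2e-05), and Gpihbp1, the capillary anchor of lipoprotein lipase, by 3.80 ± 0.48 (adjusted p = 0.0023). Of 124 endothelial-like cells in the sub-cluster richest in Plvap, 118 came from VPA libraries. They were 45 of 3750 endothelial-like cells in VPA male replicate 1 and 11 of 1167 in VPA male replicate 2. In VPA female replicates 3 and 4 they were 33 of 1611 and 29 of 1832. Without that sub-cluster 10 of the 26 genes were removed by the count filter and 1 still passed, or 3 with no gene removed by the filter, and Plpp3 stood at 0.02 (adjusted p = 1.0). For 11 of the 26, picked because nearly all of their UMIs lay outside it, leaving it out could hardly move the fold change. Their median was 1.68 with and without it, Aplp1 going from 1.35 to 1.36. Another endothelial-like cluster, led by interferon-response genes, held 15.7% of these cells in VPA and 2.28% in saline libraries on average, and came largely from VPA male replicate 1. Without it Plpp3 stood at 0.22 (adjusted p = 0.87) and Aplp1 at 1.44 (adjusted p = 0.072). Plpp3 lost its call without VPA male replicate 1 (0.84, adjusted p = 0.057) or saline male replicate 2 (0.86, 0.073), with a fold change near that of all libraries. Aplp1 lost it without VPA female replicate 4 (1.15, 0.19), VPA male replicate 1 (1.31, 0.17), VPA male replicate 2 (1.35, 0.070), saline female replicate 4 (1.16, 0.16) or saline male replicate 2 (1.15, 0.14). It was lost also with the replicate block (1.38, 0.055), with doublets kept (1.35, 0.090) and with equal cells per library (1.27, 0.087).

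**Figure D2:**
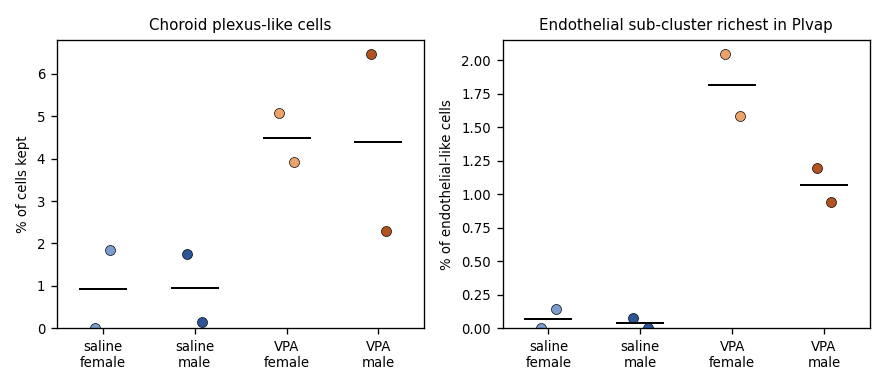
Percent of cells kept that were choroid plexus-like (first panel) and percent of endothelial-like cells that fell in the Plvap-rich sub-cluster (second panel), with 1 point for each library by treatment and sex. The VPA libraries lie above the saline libraries in both panels, and 118 of the 124 Plvap-rich cells came from VPA libraries.

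Dbp, a transcription factor driven by the circadian clock (chromosome 7, 45705088 to 45710203, plus strand), fell after VPA in 2 classes. It went from 106 ± 64.9 to 14.8 ± 5.62 CPM in endothelial-like cells (-2.79 ± 0.50, adjusted p = 0.028). In smooth muscle-like cells it went from 142 ± 90.1 to 15.3 ± 11.7 CPM (-3.04 ± 0.56, adjusted p = 0.023). Saline male replicate 1, at 13.5 and 10.8 CPM, lay within the range of the VPA libraries in both. In endothelial-like cells the call was lost without saline male replicate 2 (-2.32, adjusted p = 0.20), saline female replicate 4 (-2.78, 0.056), VPA male replicate 1 (-2.90, 0.14) or VPA female replicate 4 (-2.50, 0.071). In smooth muscle-like cells it was lost without saline male replicate 2 (-2.40, adjusted p = 0.13), saline female replicate 3 (-2.85, 0.068), VPA male replicate 1 (-3.51, 0.11), VPA female replicate 3 (-2.76, 0.094) or VPA female replicate 4 (-2.60, 0.15). DESeq2 (0.40), limma-voom (0.18) and edgeR with the replicate block (-2.67, 0.054) did not call it there.

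In all, 40 of 90340 class-gene pairs passed the edgeR test for VPA against saline, 38 higher and 2 lower, in 4 classes. An unadjusted p under 0.05 was seen in 3421. Endothelial-like cells held 27 of the 40, smooth muscle-like cells 10, pericyte-like cells 2 and committed oligodendrocyte precursor-like cells 1. For the 6 classes with 0 calls by edgeR, the genes of smallest p are given with predicted genes left aside. In OPC-like cells this was Socs3, a feedback inhibitor of cytokine signalling (-1.50, adjusted p = 0.19). In microglia-like cells it was Enpp2, the enzyme that makes lysophosphatidic acid (1.89, adjusted p = 0.17). The predicted gene 1500015O10Rik, looked up afterwards and highest in choroid plexus-like cells, lay ahead of Enpp2 there (3.44, adjusted p = 0.16). Among the rest the genes with the smallest p included Fxyd6 and PISD in astrocyte-like, Wfs1 in excitatory neuron-like, Cldn11 and Hspa1a in immature neuron-like, and Calml4 and Sema4f in oligodendrocyte-like cells, none past the threshold. Unadjusted p-values under 0.05 numbered 467 in OPC-like, 371 in astrocyte-like and 465 in excitatory neuron-like cells. They numbered 238 in immature neuron-like, 325 in microglia-like and 189 in oligodendrocyte-like cells. In these 6 classes DESeq2 called 2 genes and limma-voom 8 in microglia-like cells, limma-voom called 11 in OPC-like cells, and both called 0 in the other 4. The count of 40 became 102 without saline male replicate 1, 101 without saline female replicate 3 and 19 without VPA male replicate 1. It became 69 without VPA male replicate 2, 123 without VPA female replicate 3 and 25 without VPA female replicate 4. Without VPA male replicate 1 and VPA female replicate 4 together it was 14.

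Gene lists set before the data were examined were tested with camera, and 79 of 272 class-list pairs passed for VPA against saline, 47 higher and 32 lower. With an estimated correlation 0 passed (18 at an unadjusted p under 0.05) and by fry 0 (13 unadjusted). Each list is given with its adjusted p under the preset correlation and then, named as such, with an estimated correlation. Heat shock genes, which encode protein-folding chaperones, were higher in 9 classes. In oligodendrocyte-like cells 13 of 13 were above 0 (median 0.40, adjusted p = 2.2e-10; adjusted p = 0.556 with an estimated correlation). The same held of 13 of 13 in endothelial-like (0.57, adjusted p = 7.6e-09; adjusted p = 0.779 with an estimated correlation) and pericyte-like cells (0.47, adjusted p = 1.8e-08; adjusted p = 0.552 with an estimated correlation). Immediate early genes, transcribed within minutes of a stimulus, were lower in OPC-like cells (median -0.40, adjusted p = 2.2e-07; adjusted p = 0.779 with an estimated correlation), with 6 lower when adjusted over the list alone. Junb was at -1.30 and Fos at -1.09 there. They were also lower in oligodendrocyte-like cells (-0.28, adjusted p = 1.5e-07; adjusted p = 0.880 with an estimated correlation). In each of these classes the mean levels of the heat shock and immediate early lists overlapped between VPA and saline libraries. In excitatory neuron-like cells 74 of 75 nuclear genes of oxidative phosphorylation were above 0 (median 0.40, adjusted p = 6.3e-12; adjusted p = 0.884 with an estimated correlation). Genes of the glutamatergic synapse were lower there, 2 of 24 above 0 (median -0.63, adjusted p = 3.1e-07; adjusted p = 0.853 with an estimated correlation). Astrocyte markers in these cells stood at 5.861 to 8.021 log2 CPM in VPA and 7.004 to 8.965 in saline libraries. Saline male replicate 2 held the highest synapse mean, 8.953 log2 CPM, and the lowest oxidative phosphorylation mean, 7.369. Among the synapse genes Grin2b, an NMDA receptor subunit, was at -1.18 ± 0.42 and Slc17a7, the vesicular glutamate transporter, at -1.24 ± 0.48, neither past the threshold. Different clusters made up this class: cluster 18 held 68.5% of it in saline and 38.0% in VPA libraries on average, and cluster 26 held 13.2% and 37.8%. The median depth of its cells was 6125 UMIs in VPA male replicate 1 and 842.5 to 4191.5 in the other libraries.

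Among glial and vascular lists, inflammatory cytokine and NF-kB genes were lower in microglia-like cells, 2 of 21 above 0 (median -0.60, adjusted p = 5.8e-08; adjusted p = 0.880 with an estimated correlation). The chemokine genes Cxcl2 and Ccl7 were at -2.16 and -1.92. The libraries overlapped: saline male replicate 1 stood at 6.760 log2 CPM, the other saline ones at 7.917 to 8.726, VPA male replicate 2 at 6.042 and the other VPA ones at 6.978 to 8.284. In saline male replicate 1 and VPA male replicate 2, cluster 19 held 49.0% and 52.8% of microglia-like cells, and 3.17% to 18.8% elsewhere. Reactive astrocyte genes were lower in astrocyte-like cells, 0 of 5 above 0 (median -1.02, adjusted p = 5.6e-05; adjusted p = 0.766 with an estimated correlation). These included the intermediate filament genes Gfap (-1.20 ± 0.34) and Vim (-1.08), and 3 were lower when adjusted over the list alone. Saline female replicate 4, at 5.346 log2 CPM, lay below the VPA libraries (5.581 to 5.819), and the other saline ones above them (6.216 to 6.998). Genes of cholesterol synthesis were lower in oligodendrocyte-like cells (median -0.14, adjusted p = 7.3e-06; adjusted p = 0.515 with an estimated correlation). Blood-brain barrier genes of endothelium were higher in microglia-like cells (median 0.72, adjusted p = 2.2e-05; adjusted p = 0.880 with an estimated correlation) and lower in committed oligodendrocyte precursor-like cells (-0.47, adjusted p = 8.8e-05; adjusted p = 0.559 with an estimated correlation). In the microglia-like cells of VPA male replicates 1 and 2 and VPA female replicates 3 and 4 the barrier list stood at 4.532, 2.780, 4.651 and 5.546 log2 CPM, and at 3.517 to 5.087 in saline libraries. General endothelial markers stood at 5.188, 2.781, 5.278 and 6.054, and at 3.576 to 5.167 in saline libraries. Most of these markers, such as Cldn5 and Pecam1, are also on the barrier list, so their moving with it is no separate evidence. Ribosomal protein genes were lower in microglia-like cells, 4 of 80 above 0 (median -0.25, adjusted p = 2.3e-17; adjusted p = 0.880 with an estimated correlation). VPA male replicate 1 went the other way, at 10.539 log2 CPM, above the saline libraries (10.261 to 10.436), with the other VPA ones at 9.889 to 9.956. For histone deacetylase genes, whose products VPA inhibits, and for Wnt pathway genes the smallest adjusted p by camera was 0.127 and 0.368, both in immature neuron-like cells.

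The series title asks about genes associated with autism. Of 70 such genes on a list set beforehand 67 were measured, in 547 class-gene pairs. None passed over all genes by edgeR for VPA against saline, for male against female or for the difference of the VPA effect between the sexes. In that order 15, 35 and 8 pairs had an unadjusted p under 0.05, DESeq2 called 1, 2 and 0, and limma-voom 0 in each. Adjusted over the list alone the counts were 1, 3 and 0. The genes in these counts were read off after their values were seen. Ank2, a membrane anchor protein, was at 1.41 ± 0.30 in endothelial-like cells after VPA (adjusted p = 0.0129 over the list alone and 0.063 over all genes). The 3 for male against female were all Ddx3x, an X-linked RNA helicase that is also on the list of X-inactivation and escape genes. It was lower in male endothelial-like (-0.62), oligodendrocyte-like (-0.73) and smooth muscle-like cells (-0.66). By camera the list was lower after VPA in OPC-like cells (median -0.15, adjusted p = 0.000155; adjusted p = 0.886 with an estimated correlation) and in excitatory neuron-like cells (median -0.10, adjusted p = 0.0497; adjusted p = 0.884 with an estimated correlation). In OPC-like cells VPA male replicate 2, at 6.132 log2 CPM, lay above every saline library (5.876 to 6.025), and VPA male replicate 1 was lowest at 5.511. The members with the smallest p were Dscam (-0.35) and Phf21a (-0.37) in OPC-like and Grin2b (-1.18) and Nlgn3 (-1.14) in excitatory neuron-like cells. For the difference between the sexes it was lower in oligodendrocyte-like (-0.18, adjusted p = 0.0011; adjusted p = 0.873 with an estimated correlation) and OPC-like cells (-0.18, adjusted p = 0.0392; adjusted p = 0.928 with an estimated correlation).

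Between the sexes, genes induced by interferon, the antiviral cytokine, rose in male libraries in several classes. In pericyte-like cells Ifi27l2a, an interferon-inducible membrane protein (chromosome 12, 103442167 to 103443680, minus strand), stood at 75.3 ± 61.1 CPM in males and 2.79 ± 3.63 in females (SD, n = 4 each; 4.28 ± 0.71, adjusted p = 0.0032). Ifit3, an antiviral RNA-binding protein, stood at 85.7 ± 47.3 and 15.8 ± 9.12 CPM (2.35 ± 0.37, adjusted p = 0.0022). Rtp4, an interferon-induced chaperone of receptors (chromosome 16, 23520291 to 23614222, plus strand), was called in pericyte-like (3.55 ± 0.60, adjusted p = 0.0046), microglia-like (3.37 ± 0.56, adjusted p = 0.016) and OPC-like cells (1.87 ± 0.36, adjusted p = 0.025). Phf11d stood at 55.5 ± 18.3 CPM in male and 15.4 ± 2.86 in female microglia-like cells (1.78 ± 0.26, adjusted p = 0.0072). Isg15, a ubiquitin-like modifier named after its value was seen, was 2.75 ± 0.32 higher on the log2 scale in male pericyte-like cells (adjusted p = 3.4e-05). The call of Rtp4 in microglia-like cells was lost without saline male replicate 1 (2.67, adjusted p = 0.10), VPA male replicate 1 (3.23, 0.051), VPA female replicate 3 (3.45, 0.074) or VPA female replicate 4 (3.06, 0.11), and by limma-voom (3.31, 0.051). In OPC-like cells it was lost without saline male replicate 1 (1.60, 0.38), VPA male replicate 1 (1.59, 0.12), VPA female replicate 3 (1.71, 0.11) or VPA female replicate 4 (1.65, 0.10). It was lost there also by DESeq2 (2.02, 0.47), by limma-voom (0.85, 0.52) and with equal cells per library (1.54, 0.13). In pericyte-like cells Ifit3 lost its call with doublets kept (1.31, adjusted p = 0.74), with equal cells per library (1.89, 0.24) and by limma-voom (2.42, 0.056). Phf11d lost its call without VPA male replicate 1 and VPA female replicate 4 together (1.61, 0.083). DESeq2 and limma-voom did not call Ifi27l2a in pericyte-like cells (adjusted p = 0.16 and 0.31). Limma-voom did not call Rtp4 there (0.35), and Rtp4 was lost with predicted doublets kept (2.20, 0.30) and with equal cells per library (3.06, 0.70).

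As a list, 24 of 24 interferon genes were above 0 in male endothelial-like cells (median 1.06; 23 adjusted over the list alone). It was 20 of 20 in microglia-like (1.54; 19), 14 of 14 in pericyte-like (1.57; 12) and 15 of 16 in OPC-like cells (1.88; 14). Camera called the list higher in males in the 8 classes where it was tested, with an adjusted p of 8.4e-44 in microglia-like cells. None of these calls held with an estimated correlation (adjusted p of 0.0934 to 0.356 with an estimated correlation). Averaged over members and 8 classes, the list stood at 5.07 ± 0.588 log2 CPM in male and 3.92 ± 0.0908 in female libraries, with all 4 male libraries above all 4 female ones (exact two-sided permutation p = 0.0286, the smallest possible). Class by class this held in 3 of the 8, and in 5 saline male replicate 2 lay under at least 1 female library. Among microglia-like cells, cluster 19 held 31.3% in male and 3.68% in female libraries on average. The endothelial-like cluster led by interferon-response genes held 15.0% of that class in male and 3.04% in female libraries on average. The male mean rests on VPA male replicate 1, at 48.5%; the other 7 libraries held 0.999% to 6.42%.

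**Figure D3:**
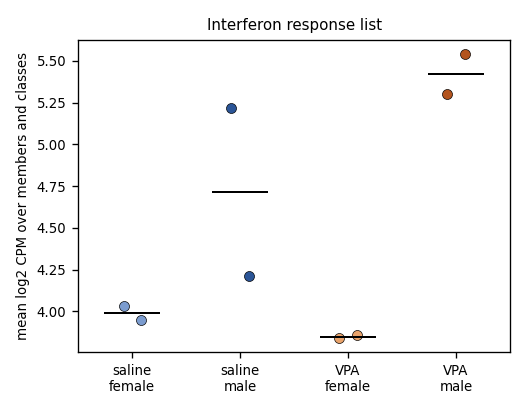
Mean log2 CPM of the interferon list over its members and 8 classes (vertical axis), with 1 point for each library by treatment and sex. The male libraries lie between 4.21 and 5.54 and the female libraries between 3.84 and 4.03.

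Haemoglobin RNA also stood apart between the sexes. Hbb-bs, a beta globin (chromosome 7, 103826534 to 103828096, minus strand), was read at 117 ± 101 CPM in male and 8.46 ± 6.77 CPM in female endothelial-like cells (3.68 ± 0.49, adjusted p = 0.0024). The call was lost with the cells of the combined matrix (3.25, adjusted p = 0.12). Looked up afterwards, Hba-a1 (3.27, adjusted p = 0.00094) and Hba-a2 (2.91, 0.023) were called there too. Hbb-bs was also called in OPC-like cells (2.51, adjusted p = 0.017). The marker genes set beforehand hold these as markers of red blood cells. Whether their RNA came from such cells was not tested. Smooth muscle-like cells of males held more RNA of Trnp1, a nuclear protein of neural progenitors (1.40 ± 0.23, adjusted p = 0.0031). This call was lost without VPA male replicate 1 and VPA female replicate 4 together (1.22, adjusted p = 0.13). They held less of the myelin gene Mbp (28.6 ± 9.48 against 59.6 ± 20.4 CPM, -1.06 ± 0.22, adjusted p = 0.040). Markers of other cells, looked up afterwards, were lower there too. The oligodendrocyte marker Mobp was at -1.39 ± 0.23 (adjusted p = 0.0053). Bcas1, a marker of committed oligodendrocyte precursors, was at -2.83 ± 0.50 (adjusted p = 0.0088). Mbp lost its call without saline male replicate 1 (adjusted p = 0.062), saline female replicate 4 (0.13), VPA male replicate 1 (0.14), VPA female replicate 3 (0.077) or VPA female replicate 4 (0.16). It lost it also with equal cells per library (-0.86, 0.15) and with the cells of the combined matrix (-0.98, 0.070), and stood at 0.01 with predicted doublets kept. In all, 103 pairs passed by edgeR, 79 higher and 24 lower in males, in 10 classes. Of these 53 were not on the lists of Y-linked and X-inactivation or escape genes. Xist was lower in males in all 10 classes, by log2 fold changes between -14.84 and -11.85. Its list of X-inactivation and escape genes was called lower in all 10 with an estimated correlation too (adjusted p of 0.0037 to 0.033). The 103 became 296 without saline male replicate 2 and 195 without VPA male replicate 2.

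Whether the VPA effect differed between the sexes was tested directly, and the 7 pairs that passed were all in pericyte-like cells. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590, minus strand), differed by -3.86 ± 0.58 on the log2 scale, with a VPA effect of -1.12 in males and 2.74 in females (adjusted p = 0.0015). Its levels were 1130 and 1190 CPM in saline male, 68.7 and 238 in saline female, 734 and 335 in VPA male and 782 and 1250 in VPA female libraries. Anxa1, a phospholipid-binding regulator of inflammation (chromosome 19, 20373428 to 20390944, minus strand; -4.15 ± 0.61), and Tagln, an actin-binding protein of smooth muscle (chromosome 9, 45929619 to 45936058, minus strand; -3.54 ± 0.52), had the same adjusted p of 0.0015. Errfi1, an inhibitor of EGF receptor signalling, differed by -2.72 ± 0.51 (adjusted p = 0.018). S100a6, a calcium-binding protein, differed by -4.66 ± 0.86 (adjusted p = 0.018). The other 2 were a predicted gene and Ccl19, a chemokine gene whose symbol is shared by more than 1 gene and whose count is uncertain. Acta2 and Tagln are markers of smooth muscle. A further 2, looked up afterwards, were at 0.30 ± 0.54 (Myh11) and -0.47 ± 0.44 (Mylk) in pericyte-like cells, neither past the threshold. In smooth muscle-like cells Acta2 was at 0.09 ± 0.36. S100a6 lost its call without saline female replicate 3 (-4.07, adjusted p = 0.093), VPA male replicate 1 (-4.45, 0.10) or VPA female replicate 4 (-4.00, 0.11), by DESeq2 (0.36), by limma-voom (0.27), with doublets kept (-4.81, 0.083) and with equal cells per library (-2.56, 1.0). Acta2 lost its call by DESeq2 (-3.85, adjusted p = 0.20) and with equal cells per library (-3.36, 0.43), and Anxa1 with equal cells (-4.06, 0.43).

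Over all classes 7 of 90340 pairs passed by edgeR for this difference, and 2562 had an unadjusted p under 0.05. The other 9 classes had 0 calls by edgeR. DESeq2 called 2 genes in endothelial-like, 1 in excitatory neuron-like and 1 in immature neuron-like cells, and limma-voom called 0 outside pericyte-like cells. The count of 7 became 104 without saline male replicate 1, 37 without saline male replicate 2, 11 without saline female replicate 3 and 32 without saline female replicate 4. It became 13 without VPA male replicate 1, 14 without VPA male replicate 2 and 62 without VPA female replicate 3. Counts were simulated with known changes in well-counted genes. There 5% of 2-fold and 56% of 4-fold differences of this kind were recovered in pericyte-like cells, and 0% of both in excitatory neuron-like cells. False calls made up 9.0% of those in pericyte-like and 13% in microglia-like cells, above the threshold of 5%. Hspb1, a heat shock gene, at -3.65 in astrocyte-like cells, was not past the threshold (adjusted p = 0.067). It passed without saline male replicate 1 (0.0043), saline male replicate 2 (0.0078), saline female replicate 3 (0.028), saline female replicate 4 (0.040), VPA male replicate 1 (6.4e-05) or VPA female replicate 3 (0.038), and stood at 0.89 with predicted doublets kept. By camera 92 of 272 class-list pairs passed, 52 higher and 40 lower in the male than in the female effect. By contrast 0 did with an estimated correlation (16 unadjusted) or by fry (10 unadjusted). The interferon list differed in endothelial-like cells, with 24 of 24 above 0 and 11 when adjusted over the list alone. Its median was 0.96 (camera adjusted p = 3.2e-35, adjusted p = 0.539 with an estimated correlation). The endothelial-like cluster led by interferon-response genes held 48.5% of that class in VPA male replicate 1 and 4.71% in VPA male replicate 2.

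Within a single sex the VPA effect rested on 2 libraries against 2, with a spread shared by all 4 groups. In males 4 pairs passed by edgeR and in females 31, with 3886 and 2226 at an unadjusted p under 0.05. Read off after their values were seen, Ttr passed in pericyte-like cells in both sexes (5.70 in males, 4.47 in females). DESeq2 and limma-voom called 0 genes in male pericyte-like cells, where edgeR called 1 and had 217 at an unadjusted p under 0.05. For female ones they called 10 and 9, and edgeR 12. In female pericyte-like cells the clock genes Dbp (-3.92), Nr1d1 (-2.75), Tef (-2.97) and Nr1d2 (-2.43) fell. A difference between the sexes did not pass for these clock genes. The male count of 4 became 522 without saline male replicate 1, 9 without saline male replicate 2, 16 without saline female replicate 3 and 15 without saline female replicate 4. It became 2 without VPA male replicate 1, 1418 without VPA male replicate 2, 18 without VPA female replicate 3 and 14 without VPA female replicate 4. The female count of 31 became 100 without saline male replicate 1, 88 without saline male replicate 2, 51 without saline female replicate 4, 204 without VPA female replicate 3 and 17 without VPA female replicate 4. Genes are not independent replicates. Across them the male and female VPA effects had a Pearson r of 0.445 and a Spearman rho of 0.197 in endothelial-like cells. In microglia-like cells r was 0.157, and the median r over the 10 classes was 0.0423. Treatment labels were swapped within a sex on differences of log2 CPM, where the real labels are 1 of 9 combinations. On that scale r was 0.367 in endothelial-like cells, against 0.252 for the largest absolute r after swapping. For microglia-like cells it was 0.198, against 0.161. The real labels gave the largest absolute r in 2 of the 10 classes.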

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

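Of the tests in this part, the 4 that set apart genes by the share of their UMIs in 1 endothelial-like sub-cluster or leave out sex-linked genes (11, 0.59, 3.51 and 5 below) were chosen after the result was seen, as were the rules that left the tests of 1.47, 0.59, 0.0286 and 0.08 undecided.

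Values of single libraries that stood far from the others of their treatment came up in 6 of the 62 groups of 4 libraries examined, where chance gives about 1 in 20. In VPA female replicate 4, 57.7% of cells were in unnamed clusters (Wilson 95% interval 57.0 to 58.4; 3.03% to 3.94% in the other VPA libraries) and 41.1% of barcodes stood in the combined deposited matrix (40.4 to 41.8; others 75.9% to 80.8%). In VPA female replicate 3, 11.7% of cells were OPC-like (10.9 to 12.6; others 2.45% to 3.87%) and 1.44% were committed oligodendrocyte precursor-like (1.16 to 1.80; others 0.463% to 0.549%). In saline female replicate 3, 3.52% of cells were immature neuron-like (3.12 to 3.96; others 2.12% to 2.20%), and in VPA male replicate 1, 1.30% were inhibitory neuron-like (1.10 to 1.53; others 0.311% to 0.440%).

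The VPA effect differed between males and females, by a test of the difference itself, for 7 genes in pericyte-like cells, and all 7 differences were below 0. They were Acta2 (-3.86), Anxa1 (-4.15), a predicted gene (-4.45), Tagln (-3.54), Ccl19 (-3.33), Errfi1 (-2.72) and S100a6 (-4.66). Of the 7, 2 were also called with equal cells per library, 4 by DESeq2, 5 with doublets kept and 6 by limma-voom. With the preset correlation 92 class-list pairs differed between the sexes as well, and 0 with an estimated correlation (16 at an unadjusted p under 0.05).

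In endothelial-like cells 26 genes were higher after VPA. If vessel cells of choroid plexus type in the Plvap-rich sub-cluster were the cause, the median log2 fold change of the 26 should have lost most of its size without them; it went from 2.24 to 1.47, but 10 of the genes then have too few UMIs for the count filter and with these at 0 it is 0.351, so this test is left undecided. For 11 of the 26 the sub-cluster held at most 2.25% of the UMIs in VPA libraries where the fold change needs 48.6% or more, which argues against it as their cause; for Cd24a, Thrsp and Ednrb it held 43.3%, 43.1% and 35.1% where 56.2%, 55.7% and 66.1% are needed, so it covers a part, and for the rest, Plvap among them, its share comes up to the need or near it and it stays a candidate explanation. Free RNA from other cells should raise the same genes alike elsewhere. The median over other classes was 0.16 for all 26. This takes in classes where a gene's own level is far higher, which would hide a small addition, so it decides nothing. Phgdh, for example, stood at 528 CPM in saline astrocyte-like and 4.98 in saline endothelial-like cells. Of the UMIs of Plvap in VPA libraries 97.2% lay in the 1 sub-cluster, which argues against free RNA as the cause for Plvap. The sub-cluster was itself picked for its Plvap level, which favours a high share, so this is no independent test. Of the 11 genes outside the sub-cluster, free RNA may account for the 2 highest in choroid plexus-like cells, 1500015O10Rik and Calml4. These stood at 3.51 in other classes with a comparable saline level and 3.27 in endothelial-like ones. For the other 9, of which 6 are highest in oligodendrocyte-like cells, 0.59 against 1.49, with a spread of 0.341, decides neither way. A VPA effect on vessel cells, a different amount of choroid plexus taken at dissection, and other cells stuck to endothelial ones stay open, the last 2 untested.

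Interferon genes were higher in male libraries. If VPA male replicate 1 were the cause, the median of the 21 called pairs should have lost most of its size without it; it was 1.83 with and 1.80 without that library, 21 of 21 stayed above 0 and 9 were still called. The mean level of the list separated the sexes completely (exact permutation p = 0.0286, the smallest possible), but the calls on the same list and libraries prompted this test, and class by class the sexes separated in 3 of 8; saline male replicates 1 and 2 lay apart at 5.22 and 4.21 log2 CPM, so a difference between libraries that ignores sex stays open. A sex difference may account for the pattern as a hypothesis, but males and females may also differ in housing, litter or day of preparation, which the labels do not give, and this was not tested.

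Dbp was lower after VPA in 6 of the 9 classes that measured it. Another clock phase at collection would lower other clock output genes and raise those of the opposite phase. Over the classes the output genes had a median of -0.38 (below 0 in 8 classes) and the opposite-phase genes one of 0.08 (above 0 in 6), within the spread of the class medians, so the test decides nothing; the rule that asks for more than that spread was set after the value was seen. Dbp fell most in endothelial-like, smooth muscle-like and pericyte-like cells (-2.79, -3.04 and -2.05). In these classes, looked up afterwards, each opposite-phase gene measured was above 0, some within their SE of 0, and each output gene below 0. The opposite-phase gene Arntl was at 1.11, 0.76 and 1.29 and Nr1d1 at -1.38, -1.52 and -1.29, none past the threshold. A clock phase effect and a VPA effect on Dbp cannot be told apart here. Over all classes the opposite-phase values lie too near 0, and times of collection are not given in the sources used here.

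For the counts of calls, other splits of the 8 libraries into 4 and 4 were refitted without sex as a term, 35 splits in each case. For VPA against saline 7 splits gave as many calls as the real one, which gave 18, and the highest other gave 104, so chance is not excluded. Some of those other splits part the sexes; of the 18 with 2 males on each side 2 gave as many, the real one included, and the highest other is the same 104. For male against female 2 splits did, with 90 for the real one and 104 for the highest other. Those 90 include Y-linked and X-inactivation or escape genes, for which Xist and the Y-linked genes, read in 1 sex and nearly absent in the other, rule chance out as the cause. Outside these lists 5 splits did, with 40 for the real one and 104 for the highest other, so chance is not excluded there. For the lists 28 splits did, with 76 for the real one and 122 for the highest other, so chance is not excluded. The split with 104 calls sets saline male replicate 1, saline female replicate 3, VPA male replicate 2 and VPA female replicate 3 against the rest. Of its calls 103 lie in oligodendrocyte-like cells. It was singled out for having the most calls, and whether a structure of the samples lies behind it was not tested.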

How the results depend on the processing

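Leaving out VPA male replicate 1 and VPA female replicate 4 together, 1 endothelial-like cluster or the Plvap-rich sub-cluster, and changing the denominator of shares, were chosen after seeing the data; the other alternatives were planned. For VPA against saline the 40 calls became 710 with no filter beyond 1 count, 24 with equal cells per library, 69 with cells of the combined matrix, 67 by DESeq2, 75 by limma-voom, 14 without both libraries (7 shared), 17 without the cluster, 14 without the sub-cluster and 19 to 123 without each library in turn. For male against female the 103 became 768 with no filter, 65 with equal cells, 158 by DESeq2 and 69 to 296 without each library. For the difference between the sexes the 7 became 220 with no filter, 23 with the stricter cell filter, 24 with combined-matrix cells, 24 with the replicate block, 13 without both libraries and 9 to 104 without each library. The 4 calls in males became 582 with no filter, 12 with combined-matrix cells, 66 by DESeq2, 0 by limma-voom (edgeR had 3886 at an unadjusted p under 0.05), 49 with the block and 2 to 1418 without each library. The 31 in females became 441 with no filter, 12 with doublets kept, 16 with equal cells, 19 by DESeq2, 47 by limma-voom, 62 with the block, 16 without both libraries and 17 to 204 without each library. Without the filter more genes are tested and without a library fewer samples; for the rest the cause was not tested. Where leaving out a library left a group with 1 sample, that sample was assumed to vary like the other groups. The 79 and 92 class-list pairs became 0 and 0 with an estimated correlation and 0 and 0 by fry; the preset correlation is 0.01, and the median estimated one was 0.268 and 0.256. The count of shares called for VPA was 1 without saline male replicate 1 and 0 otherwise. Reversed with doublets kept were Hspb1 in astrocyte-like cells (difference between the sexes, 0.89 for -3.65) and Mbp in smooth muscle-like cells (male against female, 0.01 for -1.06); the cause was not tested. Deviations of same-numbered libraries had a median r of -0.00322 in males and -0.00708 in females over 10 classes. Single classes ranged from -0.0425 to 0.257 in males and from -0.254 to 0.328 in females. The highest were committed oligodendrocyte precursor-like cells in males and oligodendrocyte-like cells in females, so the medians do not exclude a pairing in single classes. With the replicate block there were 48 calls for VPA against saline and 86 and 96 class-list pairs. Over the named genes and shares and all alternatives, 1747 values kept their direction and side of the threshold, 176 lost it, 77 gained it and 2 reversed. Those kept include Xist and Y-linked genes, and genes not past the threshold that stayed so. The tally therefore says little of how stable the VPA calls were. Of simulated 4-fold differences between the sexes 0% were recovered in excitatory neuron-like cells; the cause was not tested.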

Other observations

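The genes given here within a sex were looked up after their values were seen, and no hypothesis is tested in this part.

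In female libraries the chaperone genes Hspb1 and Hspa1a were higher after VPA in astrocyte-like cells, by 3.26 ± 0.46 (adjusted p = 0.0014) and 2.51 ± 0.45 (adjusted p = 0.011) on the log2 scale, and Ttr by 6.83 ± 1.21 in the same cells (adjusted p = 0.011). In that class and sex edgeR called 6 genes, DESeq2 0 (edgeR had 432 at an unadjusted p under 0.05) and limma-voom 1. In female smooth muscle-like cells Nr1d1, a repressor of the clock, was lower (-3.40 ± 0.56, adjusted p = 0.0093) beside Dbp (-5.15 ± 0.84, adjusted p = 0.0093), and the tight junction gene of myelin Cldn11 was higher (3.49 ± 0.58, adjusted p = 0.0093). In male endothelial-like cells the interferon-induced Ifit3 was higher after VPA (1.83 ± 0.28, adjusted p = 0.046) and the histone gene Hist1h4d lower (-1.43 ± 0.22, adjusted p = 0.046). Of the 4 edgeR calls in males 0 were kept without VPA male replicate 1, and limma-voom called 0 in males (edgeR had 3886 at an unadjusted p under 0.05); the endothelial-like cluster led by interferon-response genes held 48.5% of the class in VPA male replicate 1 and 4.71% in VPA male replicate 2. By edgeR a difference between the sexes did not pass for these genes in these classes. DESeq2 called it for Ifit3 (1.85, adjusted p = 0.014) and Hist1h4d (-1.89, adjusted p = 0.010) in endothelial-like cells, and edgeR called it for Hspb1 in astrocyte-like cells with the stricter cell filter (-4.09, adjusted p = 0.0013) and with cells of the combined matrix (-4.19, adjusted p = 0.00051), while with doublets kept it stood at 0.89 (adjusted p = 1.0).

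As a list, immediate early genes had a lower VPA effect in males than in females in pericyte-like cells (median -1.66, camera adjusted p = 4.2e-11, adjusted p = 0.657 with an estimated correlation; 4 lower when adjusted over the list alone). The replicates lay far apart, at 6.875 and 8.994 log2 CPM in saline male and 6.401 and 8.048 in saline female libraries. Myelin genes did so in astrocyte-like cells (median -2.76, camera adjusted p = 9.9e-44, adjusted p = 0.539 with an estimated correlation; 13 when adjusted over the list alone). There saline male replicates 1 and 2 stood apart at 4.684 and 7.538 log2 CPM, the second from 67 cells, with VPA male libraries at 4.878 and 5.304, saline female ones at 5.797 and 4.405 and VPA female ones at 7.380 and 6.978, so the male part of the difference rests on saline male replicate 2. Oligodendrocyte markers, all of them members of the myelin list, are no separate evidence. In these cells they stood at 4.537 and 8.156 log2 CPM in saline male and 4.798 and 5.672 in VPA male libraries. In saline female libraries they stood at 5.842 and 4.421, and in VPA female ones at 7.972 and 7.314. Interferon genes had a higher one in committed oligodendrocyte precursor-like cells (median 2.88; camera adjusted p = 1.9e-10, adjusted p = 0.539 with an estimated correlation; 4 adjusted over the list alone). None of the 272 pairs passed with an estimated correlation by camera, 16 had an unadjusted p under 0.05, and fry called 0.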
